A study of Mus musculus with 4 samples.

How the data were processed

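Single-cell RNA was measured by 10x droplet sequencing in kidneys of 4 male mice, 1 per group: term or preterm birth, with or without streptozotocin diabetes. Per the labels, kidneys were perfused with saline, digested on ice with a cold-active protease, cleared of red cells and sorted for live cells with propidium iodide; no strain is given. The deposited count matrices hold UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10 and handled in Seurat 5.1.0, per the submitters' processing notes. All 4 held counts of 32285 genes, and barcodes with under 500 UMIs were absent. Of these genes 32235 had their identifier in GENCODE M21, used for positions.

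Barcodes with at least 200 genes and under 50% mitochondrial counts were kept (9892), and Scrublet then removed 21 (0.212%), which is too few for doublets to count as removed. The remaining 9871 cells were scaled to 10000 counts and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave 21 clusters of the 4 libraries together, without batch correction (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9). Clusters were named from marker genes fixed before the data were examined. A marker counted when detected in 10% of cells and at 25% of its highest cluster, and a name needed 40% of at least 5 measured markers and 3 or more. These limits, and the merging of classes, were set after the clusters had been seen, with several scoring forms and resolutions 1 and 2 tried.

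UMIs were summed per class and library and divided by the sum over genes other than the 13 encoded by mitochondrial DNA (CPM). Log2 ratios used a pseudocount of 1 CPM. The comparisons were diabetic against non-diabetic at term and preterm, preterm against term without and with diabetes, and the difference of the diabetic log2 ratios. With 1 animal per group no test was made and no p-value or count of changed genes is given. An additive fit of birth and diabetes would leave 1 residual degree of freedom, which is the difference in response itself, and was not run; that difference has none. Intervals are 95%: exact Poisson for levels, conditional binomial for ratios, exact binomial for shares, and resampling (10000 draws) for differences. A level of 0 was set to a floor of 3 UMIs for ratios. Gene lists, 35 in all, were fixed beforehand, and 603 of their 608 genes are in the matrices. Members with a mean of 10 CPM or more over the 4 libraries were used, and each list is described by members at least 1.5-fold apart with the counting interval off 1, by the median log2 ratio, by a bootstrap over members (2000 draws) and by the percentile of the median among 10000 random lists matched on expression in 10 bins. Lists tied to podocytes, principal, intercalated or mesangial cells were not analysed because these classes held too few cells, and a class needed 20 cells in each library for lists and 50 for named genes.

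Named genes were set by a rule fixed before the data were examined. A gene needed a mean of 20 CPM over the 4 libraries of the class, 60 UMIs, and a highest level at least 0.5 times that of the whole library; mitochondrial, ribosomal, haemoglobin, predicted, Xist and Y-linked genes and the immediate early and heat shock lists were left out. For diabetes and for birth it needed the same direction in both comparisons with counting intervals off 1, and genes were ranked by the smaller of the absolute log2 ratios. For the difference, the interval had to exclude 0, and genes were ranked by its size. The proximal tubule gives 10 genes per direction for diabetes and for birth and 5 for the difference, and other classes give 3 and 2; not every gene the rule gives is described here. Genes outside the rule that illustrate a list, and the choice of which lists lead the text, were picked after values were seen.

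The counting steps were tested on simulated data: Poisson sums drawn from the mean profile of the libraries at whole-library sizes, with known 2-fold and 4-fold changes in the diabetic libraries. No variation between animals or cells was simulated. Sums per class are smaller, down to 105278 UMIs outside mitochondrial genes in endothelium of PT-D, and recovery at those sizes was not tested. Of 6689 genes, 200 were changed, and 100 of 100 were recovered at each fold in both diabetic comparisons. Counting intervals held the true ratio for 94.0, 89.0 and 95.1% of genes at 2-fold, 4-fold and no change at term, and for 95.0, 98.0 and 95.6% in the preterm pair. Of unchanged genes, 7.61 and 6.90% had an interval off 1, so intervals do not stand in for a test.

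The alternatives were 12 set beforehand and 2 added after seeing the data: the 5% of cells with the highest doublet scores removed, and proximal tubule cells matched on mitochondrial share in bins of 5 points. Those set beforehand were mitochondrial share under 25%, 500 genes per cell, doublets kept, resolution 2, separate clustering, CPM over all genes, median ratio scaling, a mean over cells, a pseudocount of 10 CPM, members with 1 UMI, and S1 with S2 or S3 clusters alone. The test of gene span was added after the trend was seen, and the fixed members and drop intervals of the p53 tests after their values were seen. Barcodes above the mitochondrial limit enter only the counts of barcodes.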

Results

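Single-cell RNA sequencing was carried out on whole kidneys of 4 male mice, 1 from each of 4 groups. T-ND was born at term and was not diabetic, and T-D was born at term and received streptozotocin, a toxin that kills the insulin-producing cells of the pancreas and so raises blood glucose. PT-ND and PT-D were the non-diabetic and the diabetic mouse born before term. The deposited matrices held 3727 barcodes and 18377567 UMIs (counted RNA molecules) in T-ND, 5065 and 26969710 in T-D, 3810 and 25894502 in PT-ND, and 4742 and 15088179 in PT-D. After filtering, 2619, 1873, 3180 and 2199 cells were kept in that order, with medians of 3839, 5845, 4095 and 2857 UMIs per cell. With 1 animal per group there was no replicate check and no test. Every interval below is a 95% interval. Bootstrap intervals over list members show the spread among genes, and all others cover counting error only. Levels are CPM: the UMIs of a gene, summed over the cells of a class and scaled to the total of genes not encoded by mitochondrial DNA. Series of 4 values follow the order term non-diabetic, term diabetic, preterm non-diabetic, preterm diabetic. All libraries held transcripts of the Y-linked gene Ddx3y (79.8, 67.9, 63.1 and 63.3 CPM over all kept cells) and between 0 and 4 UMIs of Xist, the RNA of the inactive X chromosome, as the male labels require.

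Barcodes rich in mitochondrial RNA, a sign of damaged cells, were more frequent in the diabetic libraries. Their share at 50% or more mitochondrial counts was 29.5% (exact binomial interval 28.1 to 31.0%) in T-ND, 62.9% (61.6 to 64.2%) in T-D, 16.5% (15.3 to 17.7%) in PT-ND and 53.5% (52.0 to 54.9%) in PT-D. Barcodes at 50% or more numbered 1100, 3186, 628 and 2536, and those with under 200 genes 416, 2567, 205 and 1778. In both diabetic libraries most of the former also had under 200 genes, so that the shares mix damaged cells with gene-poor barcodes. Both kinds of barcode were removed, and the cells kept had median mitochondrial shares of 23.2, 23.01, 23.4 and 26.9%.

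Kidney tubule cells made up most of each library. Proximal tubule-like cells, which reclaim most of the filtrate, were 63.5% of kept cells in T-ND (exact binomial interval 61.6 to 65.3%), 56.4% in T-D (54.2 to 58.7%), 62.3% in PT-ND (60.6 to 64.0%) and 75.3% in PT-D (73.4 to 77.1%). Cells of the thick ascending limb, the segment that dilutes the urine, were 15.8, 13.8, 12.2 and 5.18%, and those of the distal convoluted and connecting tubule 7.60, 6.46, 7.55 and 4.37%. Among immune cells, the class of macrophages, monocytes and dendritic cells was larger in both diabetic libraries, at 8.76% in T-D (7.51 to 10.1%) against 4.2001% in T-ND (3.46 to 5.04%), and 7.05% in PT-D (6.01 to 8.20%) against 4.50% in PT-ND (3.80 to 5.28%). With each library clustered by itself, this share was 5.07% in T-D and 4.43% in T-ND, so that the term difference was small, and 6.64% in PT-D and 3.77% in PT-ND. Neutrophils were 3.47, 5.50, 5.53 and 5.09%, endothelial cells 3.55, 4.86, 4.21 and 1.68%, and T and NK cells 1.07, 3.10, 1.54 and 0.682%. Antibody-secreting plasma cells were 1.86% of PT-ND (1.42 to 2.39%), 0.427% of T-D and 0.5002% of PT-D, and 0 of 2619 cells in T-ND (exact binomial upper limit 0.141%). Clustered by itself, T-D had 1.98% plasma cells and PT-ND and PT-D had 0, while B cells made up 2.58% of PT-ND. Mesangial, pericyte and smooth muscle cells (0.535, 0.587, 0.220 and 0.0910%) and B cells (0.267, 0.107, 0.0943 and 0.0455%) were few. Protease digestion on ice, lysis of red cells, a sort for live cells and the removal of barcodes rich in mitochondrial RNA all came before these shares and can set them.

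**Figure D1:**
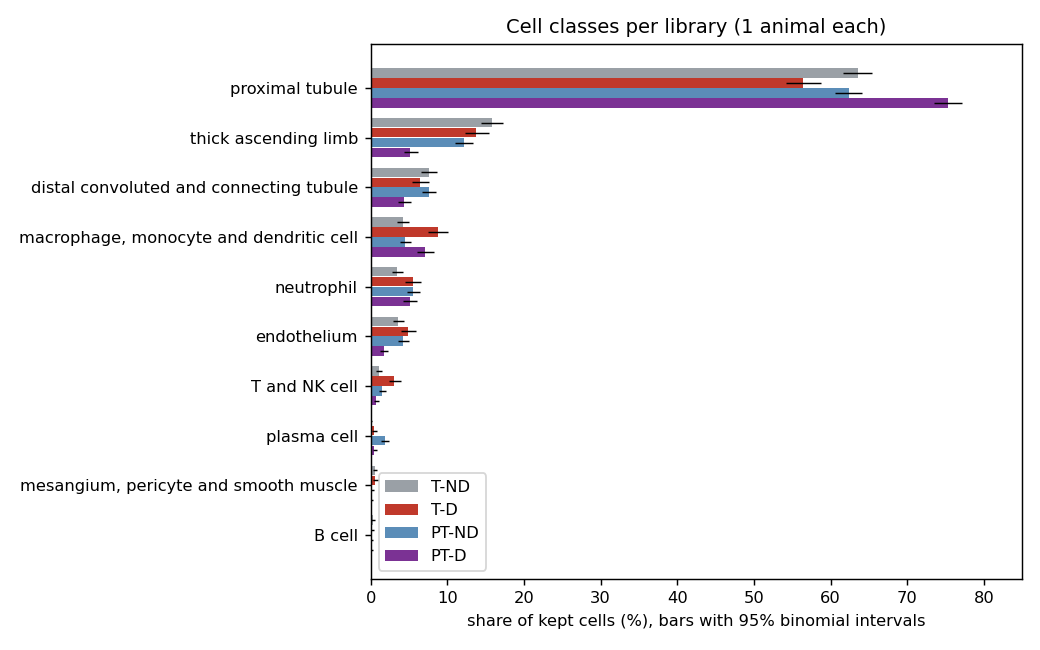
Share of kept cells (%) in each cell class (vertical axis) for the 4 libraries; bars start at 0 and error bars are 95% exact binomial intervals, 1 animal per group. Proximal tubule-like cells range from 56.4% in T-D to 75.3% in PT-D.

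Glomerular cells, which the series title is about, were scarce. Podocytes formed no cluster, and only 1, 5, 2 and 0 cells carried at least 4 podocyte markers. Cells with at least 4 markers of principal cells numbered 13, 2, 7 and 0, and those with 4 of intercalated cells 6, 1, 6 and 1. The comparisons that follow therefore concern tubule, immune and endothelial cells.

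T-ND stood apart from the other libraries inside the proximal tubule class. Clusters 0 and 2 held 91.0% of its proximal tubule cells, against 1.61% in T-D, 0.505% in PT-ND and 1.81% in PT-D, whose cells lay mostly in clusters 1, 13, 15, 16 and 19, with 264 of the 461 cells of cluster 12 from PT-D. Immune response genes were among the 10 genes that lead clusters 0 (Igtp, H2-DMb1, Cfb) and 2 (Gbp6, Gbp10, Ciita). Over 3452 genes at 50 CPM or more, the SD of log2 ratios in the proximal tubule was 0.71, 0.82 and 0.73 for the pairs with T-ND and 0.45, 0.36 and 0.53 for the pairs without it. In the thick ascending limb, 163 of the 190 cells of cluster 9 came from T-ND and 3 of the 281 of cluster 18. Comparisons of T-D or PT-ND with T-ND cannot be made without that library.

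The first question is how kidney cells of a diabetic mouse differ from those of a non-diabetic mouse of the same birth group, T-D against T-ND and PT-D against PT-ND. In proximal tubule cells, p53 target genes, which respond to DNA damage and other stress, were higher in both diabetic libraries. Of the 12 members measured, 7 were at least 1.5-fold higher and 2 lower at term (median log2 ratio 0.84, percentile 100 among random lists), and 8 were higher and 0 lower in the preterm pair (median 0.81, percentile 100). Cdkn1a, which encodes the cell cycle inhibitor p21 and is also on the tubular injury and senescence lists, led the genes named by rule: 8.53, 81.9, 12.5 and 131 CPM, 9.60-fold higher at term (7.41 to 12.6) and 10.5-fold in the preterm pair (8.77 to 12.7). Of 4 other classes measured, 0 had it 2-fold higher in both comparisons. It was at 203, 123, 65.4 and 199 CPM in the thick ascending limb and at 75.8, 76.1, 29.8 and 107 in the distal convoluted and connecting tubule. In macrophages, monocytes and dendritic cells it was at 650, 191, 142 and 228, and in neutrophils at 66.9, 38.5, 53.3 and 89.4. Ccng1 was at 63.9, 257, 122 and 255 CPM, and Trp53inp1 at 46.1, 102, 44.2 and 141 CPM. Fas (113 and 11.9 CPM in T-ND and T-D) and Gdf15 (59.2 and 25.9) were the 2 lower at term. Bootstrap intervals over members ran from −0.29 to 1.58 at term and from 0.39 to 1.03 in the preterm pair. The T-ND clusters given S3 and S1 with S2 names, 0 and 2, both met the general proximal tubule list best. They also differ in depth (medians of 3417 and 8773 UMIs), so that within-segment values at term mix segment with depth. In S3 clusters alone the term median was 0.36 over the same 12 members (0.45 over members measured there), and with a pseudocount of 10 CPM the preterm median was 0.52.

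Genes of the respiratory chain and of glycolysis had medians above 0 in both diabetic comparisons, although most members lay within 1.5-fold. The quartile of genes with the shortest span had medians of 0.21 and 0.17 in these comparisons, and the random lists were matched on expression and not on span. Of 30 nuclear genes of the respiratory chain, 3 were 1.5-fold higher at term and 7 in the preterm pair and 0 lower in either, with medians of 0.36 and 0.43 (percentiles 99.4 and 100). For glycolysis, 4 of 11 were higher and 1 lower in each pair (medians 0.42 and 0.35, percentiles 98.7 and 97.6), among them the lactate dehydrogenase subunit gene Ldhb at 734, 1211, 893 and 1435 CPM. Gluconeogenesis, the making of glucose, had 2 of 12 members higher at term and 3 in the preterm pair and 0 lower (medians 0.32 and 0.18, percentiles 95.4 and 84.3), and its bootstrap intervals over members, −0.03 to 0.55 and −0.04 to 0.64, include 0. Its rate-limiting gene Pck1 was at 1064, 1556, 1477 and 2419 CPM, and G6pc, which releases free glucose, at 137, 416, 806 and 622, lower in PT-D than in PT-ND. Within the clusters given an S3 name alone, the term medians of glycolysis and the respiratory chain turned to −0.02 and −0.08.

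Other genes higher in proximal tubule cells of both diabetic libraries were Apob, the structural protein of lipoproteins, at 16.4, 122, 31.1 and 198 CPM (7.47-fold, 6.18 to 9.09, at term and 6.38-fold, 5.65 to 7.21, in the preterm pair), and Ddit4, a stress-induced inhibitor of the growth kinase mTOR, at 2.80, 57.5, 8.39 and 33.5 CPM. Fabp3, a carrier of fatty acids, was 2.33-fold and 3.66-fold higher, the laminin gene Lama3 11.2-fold and 2.67-fold, and the reductase gene Akr1e1 4.83-fold and 2.56-fold. The cytochrome P450 genes Cyp2a5 (5.31-fold and 3.10-fold) and Cyp2d9 (7.03-fold and 2.33-fold) belong to families of near-identical copies among which reads can be split. Nckap5 was 2.44-fold and 2.42-fold higher. Apob is among the 10 genes that lead clusters 1 and 12, both given an S1 and S2 name. Cluster 1 held 27, 262, 222 and 452 cells and cluster 12 held 74, 63, 60 and 264. Cyp2d9 is among the leading genes of cluster 19, which held 7, 258, 448 and 192 cells. For Apob and Cyp2d9 a higher level was not separated from the mix of clusters. Ttr, the carrier of thyroxine, rested on 1 UMI in T-ND, with a ratio of 1015 (182 to 40119) at term and 3.09 (2.07 to 4.65) in the preterm pair. In the GRCm38 assembly Cdkn1a (ENSMUSG00000023067) spans chromosome 17, 29090976 to 29100727, on the plus strand, and Apob (ENSMUSG00000020609) spans chromosome 12, 7977648 to 8016835, plus strand; both are protein-coding, and counts are per whole gene.

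Lower in both diabetic libraries were Inmt, a methyltransferase of indole amines, at 483, 161, 533 and 95.7 CPM (3.00-fold and 5.56-fold lower), and Aoah, an enzyme that inactivates bacterial lipopolysaccharide, at 473, 143, 257 and 99.2 CPM (3.31-fold and 2.59-fold lower). Tnfsf10, the death ligand TRAIL, was at 248, 27.0, 15.4 and 3.06 CPM, and Snhg11 at 127, 13.8, 49.4 and 1.63. B4galt5 (3.18-fold and 2.73-fold lower) and St8sia6 (3.13-fold and 2.89-fold lower) add sugars to glycans. Hnf4g, a nuclear receptor, was 2.69-fold and 3.23-fold lower, and Gsap, Ubash3b and Ccser1 completed the 10 genes. Long genes were lower as a whole in both: the median log2 ratio of the quartile of genes with the longest span lay below that of the shortest by −0.45 at term and −0.39 in the preterm pair. Malat1, a nuclear RNA, was at 34061, 26476, 32120 and 22615 CPM. Within S3 clusters alone the term log2 ratios of Gsap (0.13), Ubash3b (0.34), Ccser1 (1.42), Hnf4g (3.18) and Aoah (0.62) were above 0.

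**Figure D2:**
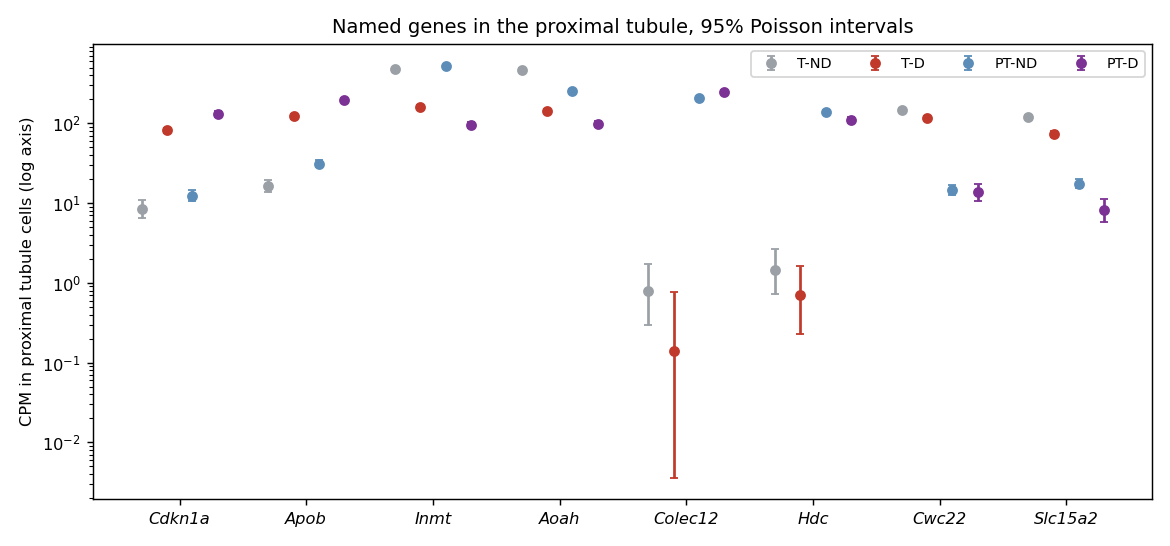
CPM in proximal tubule cells (log axis) of 8 genes named by rule, for the 4 libraries; points are sums over cells of 1 animal each and bars 95% exact Poisson intervals. Cdkn1a stands at 81.9 and 131 CPM in the diabetic libraries and at 8.53 and 12.5 in the others.

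Immune response genes differed between the birth groups in their relation to diabetes. All 24 interferon response genes measured in the proximal tubule were lower in T-D than in T-ND (median log2 ratio −2.77, percentile 0), and all 24 were higher in PT-D than in PT-ND (median 1.98, percentile 100). Ifit1, an antiviral RNA-binding protein, was at 297, 58.3, 14.3 and 214 CPM, and Isg15, a ubiquitin-like modifier, at 199, 24.0, 3.39 and 48.8. Inflammatory cytokine and NF-kB target genes were lower at term in 13 of 13 (median −3.09) and higher in 9 and lower in 0 in the preterm pair (median 0.95), with the chemokine gene Cxcl10 at 1843, 200, 88.3 and 414 CPM and the adhesion gene Icam1 at 239, 27.1, 16.8 and 33.3. Class I antigen presentation was lower in 10 of 10 at term (median −2.88) and higher in 8 and lower in 0 in the preterm pair (median 1.04), with H2-K1 at 757, 90.6, 71.6 and 98.6 CPM and B2m at 1212, 400, 238 and 413. Immediate early genes, which also respond to tissue dissociation, had 12 of 15 lower at term (median −1.69) and 8 higher and 0 lower in the preterm pair (median 0.81), with Jun at 330, 60.7, 23.4 and 53.9 CPM. These values compare T-ND cells of clusters 0 and 2 with cells of the other clusters. Over the alternatives the medians came nearest to 0 at −1.47 (term, members with 1 UMI or more) and 0.57 (preterm, S1 and S2 clusters) for inflammatory genes, and in S3 clusters at −1.90 and 0.52 for class I presentation and at 0.25 (preterm) for immediate early genes.

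**Figure D3:**
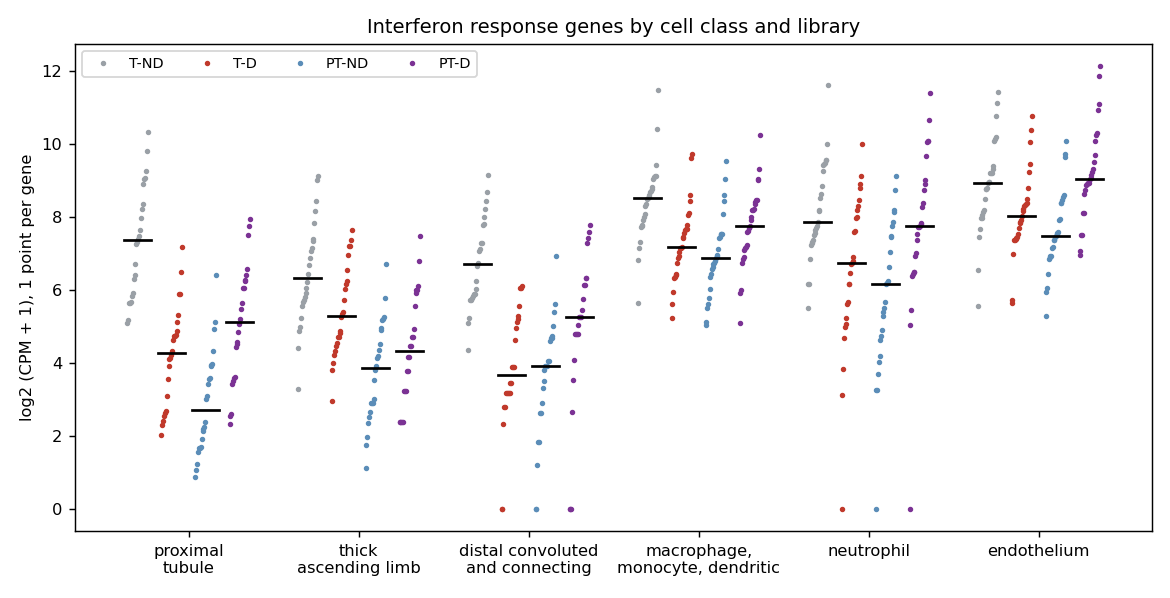
Level of each interferon response gene as log2 (CPM + 1) (vertical axis) in 6 cell classes and 4 libraries; 1 point per gene, black lines mark medians over genes. In the proximal tubule the list median is lowest in PT-ND, and all 24 genes are lower there than in T-ND and PT-D.

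Fatty acid oxidation genes and targets of the lipid sensor PPAR alpha were lower as a group in PT-ND than in PT-D and T-ND. In PT-D against PT-ND 12 of 23 were higher and 1 lower (median 0.59, percentile 100), and in T-D against T-ND 2 were higher and 3 lower (median −0.01, percentile 32.5). Acaa2, the last enzyme of the mitochondrial pathway, was at 236, 172, 59.6 and 295 CPM, Cyp4a10, a fatty acid hydroxylase and PPAR alpha target, at 160, 127, 25.4 and 202, and Hadha at 108, 107, 65.8 and 123. The lipid droplet gene Plin2 was at 116, 12.9, 44.7 and 57.8 CPM. PT-ND held the lowest level of Acaa2, Cyp4a10 and Hadha among the libraries. The difference between the birth groups, preterm minus term, had a median of 0.76 (bootstrap over members 0.33 to 1.15) and could not be tested between animals.

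Male-biased and androgen-responsive kidney genes moved in opposite directions. In T-D against T-ND, 7 of 14 were higher and 0 lower (median 0.58, percentile 100), and in PT-D against PT-ND, 0 were higher and 13 lower (median −1.26, percentile 0). Kap, an androgen-regulated gene of the proximal tubule, was at 29701, 46451, 59368 and 25790 CPM, Odc1, the first enzyme of polyamine synthesis, at 442, 1161, 3379 and 1037, and Slco1a1, an organic anion transporter, at 288, 498, 929 and 267. Kap and Odc1 are among the 10 genes that lead cluster 13, and Kap is among those of cluster 19, both with S3 markers. Clusters given an S3 name held 996 of 1663, 622 of 1057, 1493 of 1982 and 828 of 1656 proximal tubule cells. That was a larger part in PT-ND than in PT-D. In T-ND, however, 953 of these cells lay in cluster 0, and only 33 and 7 in clusters 13 and 19. Cluster 0 met the general proximal tubule list best, so that its segment is uncertain. Its 10 leading genes held the S1 and S2 marker Slc22a8 and neither Kap nor Odc1. Within clusters given an S1 and S2 name the medians were −0.22 at term, a reversed direction, and −0.40 in the preterm pair. Within S3 clusters the preterm median was −0.75.

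**Figure D4:**
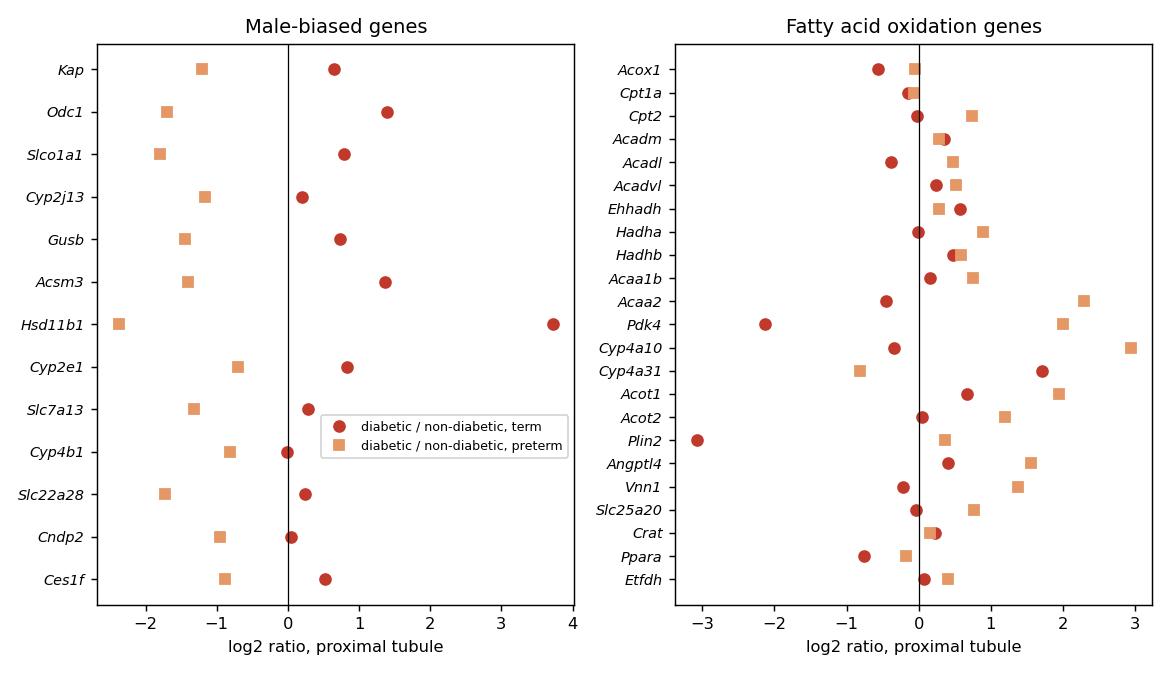
Log2 ratio of diabetic to non-diabetic library in proximal tubule cells (horizontal axis) for 13 of the 14 measured male-biased genes (left) and each measured fatty acid oxidation gene (right); circles are the term pair and squares the preterm pair. Of the male-biased genes, 13 of 14 were at least 1.5-fold lower in the preterm pair.

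Tubular injury genes were higher in 4 of 8 and lower in 0 in the preterm pair (median 0.61, percentile 100; 0.28 with the mean over cells), and higher in 1 and lower in 3 at term (median −0.16). Spp1, which encodes osteopontin, was at 315, 293, 61.9 and 808 CPM, and Vcam1 at 148, 7.41, 3.22 and 6.33. Glucose and polyol handling had 4 of 10 members higher and 0 lower in the preterm pair (median 0.39, percentile 99.2) and 1 higher and 2 lower at term (median 0.02, mean −0.29). The glucose transporter gene of the early proximal tubule, Slc5a2, was at 398, 481, 370 and 615 CPM, and the glucose-responsive gene Txnip at 94.7, 23.8, 1.61 and 28.6. Oxidative stress and NRF2 targets had 6 of 25 higher and 1 lower in the preterm pair (median 0.34) and 0 higher and 3 lower at term (median 0.25, mean −0.06), with the glutathione transferase gene Gsta2 at 79.9, 32.3, 14.4 and 196 CPM.

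The remaining lists of the proximal tubule are given as medians of the diabetic comparisons, term first and preterm second. Cholesterol synthesis had medians of −0.36 and 0.02 (13 genes, percentiles 1.67 and 54.9), lipogenesis 0.42 and −0.21 (7 genes), ketone body metabolism −0.06 and −0.21 (8 genes; mean at term 0.17), hypoxia targets 0.23 and 0.00 (11 genes), and endoplasmic reticulum stress 0.18 and −0.22 (19 genes). Heat shock genes had medians of 0.24 and −0.36 (11 genes, percentiles 81.9 and 0.875), endocytosis 0.05 and 0.28 (14 genes; mean at term −0.04), solute transporters 0.18 and −0.16 (26 genes), and matrix genes 0.06 and −0.37 (9 genes, percentiles 48.7 and 1.31; mean at term −0.27). Mitochondrially encoded transcripts had medians of 0.11 and 0.09 (13 genes; preterm mean −0.11). Few members were measured for senescence (4 genes, −0.39 and 0.29), cell cycle (4 genes, 0.43 and 0.42, the first −0.34 over members with 1 UMI or more), female-biased genes (3 genes, −0.22 and 0.28), vitamin D and phosphate handling (8 genes, −0.06 and −0.16) and nephron development (5 genes, 0.02 and −0.30). Means had the opposite sign for senescence (0.29) and nephron development (−0.65) at term and for female-biased (−0.05) and vitamin D genes (0.01) in the preterm pair. Over all genes the diabetic effects at term and in the preterm pair, which share no library, had a Pearson r of −0.0913 and a Spearman rho of 0.133 across 3452 genes, with the same sign in 58.6%; genes are not independent replicates.

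**Figure D5:**
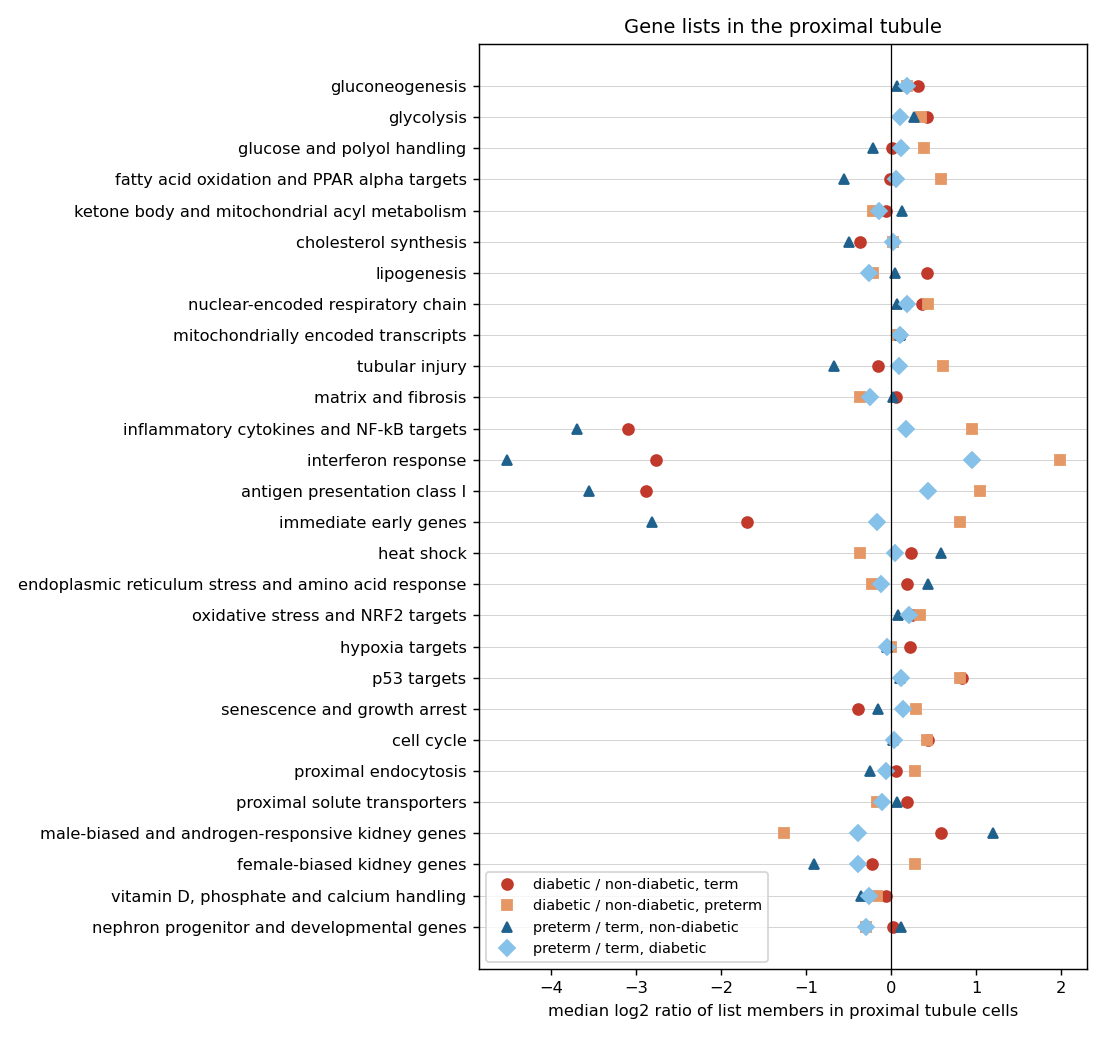
Median log2 ratio over list members in proximal tubule cells (horizontal axis) for 28 gene lists and 4 comparisons; 1 animal per group, no error bars. Interferon response medians are −2.77 and 1.98 for the diabetic comparisons at term and preterm, while p53 targets stand at 0.84 and 0.81.

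The next question is how cells of mice born before term differ from those born at term, PT-ND against T-ND and PT-D against T-D. Colec12, a scavenger receptor of the collectin family, was detected at high level in proximal tubule cells of the preterm mice alone: 0.8001, 0.140, 209 and 247 CPM, a ratio of 261 (120 to 711) without diabetes and of 1764 (316 to 69737) with it, the last against 1 UMI in T-D. Hdc, which makes histamine, stood at 1.47, 0.699, 141 and 110 CPM. Hdc is also a neutrophil marker, at 1904, 1684, 1165 and 1870 CPM in neutrophils. Its fellow marker S100a8 was at 3.87, 8.11, 36.9 and 6.74 CPM in proximal tubule cells, and did not follow Hdc in PT-D. Dnase1, which encodes a secreted DNase, was 4.93-fold (4.72 to 5.14) and 2.95-fold (2.83 to 3.08) higher, and Slc12a2, a sodium, potassium and chloride cotransporter, 6.08-fold and 2.40-fold. Clec2h, Mcfd2, Cdhr2, Nat8f1, Apob and Pbld2 completed the 10 higher genes, with ratios from 1.62-fold to 9.20-fold.

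Lower in both preterm libraries were Cwc22, a splicing factor, at 147, 117, 14.7 and 13.9 CPM (9.98-fold and 8.46-fold lower), and Slc15a2, a transporter of small peptides, at 121, 74.1, 17.6 and 8.17 CPM (6.88-fold and 9.07-fold lower). Dock10 was 6.25-fold and 7.86-fold lower, Pm20d1, an enzyme of N-acyl amino acids, 3.08-fold and 4.66-fold, and Col6a6, a collagen VI chain, 2.03-fold and 3.58-fold. Tnfsf10, Zfp951, Snhg11, Clba1 and Tmem14c were the other 5. Colec12, Cwc22 and Slc15a2 differed by 2-fold or more in the same direction in each of the 4 other classes in which they were measured. Colec12 (ENSMUSG00000036103) lies on chromosome 18, 9707595 to 9882644, plus strand, Cwc22 (ENSMUSG00000027014) on chromosome 2, 77881159 to 77946375, minus strand, and Slc15a2 (ENSMUSG00000022899) on chromosome 16, 36750177 to 36784962, minus strand. Within S3 clusters alone, Apob was not higher in PT-D than in T-D (log2 ratio −0.26), and Dock10 (1.40), Zfp951 (3.22), Snhg11 (3.06) and Col6a6 (0.22) were above 0 in PT-ND against T-ND, as was Snhg11 in PT-D against T-D (1.30).

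Immune response genes were lower in PT-ND than in T-ND, and the interferon list among them was higher in PT-D than in T-D. Of the interferon response genes, 24 of 24 were lower without diabetes (median −4.52, percentile 0), and 16 were higher and 0 lower with it (median 0.96, percentile 100). The medians were −3.69 and 0.18 for inflammatory genes, −3.56 and 0.43 for class I presentation, and −2.82 and −0.16 for immediate early genes. In PT-D against T-D most members of these 3 lists lay within 1.5-fold: 2 of 13 inflammatory genes were higher and 1 lower, 3 of 10 class I genes higher and 0 lower, and 0 of 15 immediate early genes higher and 2 lower. In S3 clusters alone class I presentation was at −0.11 in that comparison. Male-biased genes had 11 of 14 members higher and 0 lower in PT-ND (median 1.20) and 0 higher and 4 lower in PT-D (median −0.39), and within S1 and S2 clusters the first of these medians was −0.26. Fatty acid oxidation genes had 1 of 23 higher and 11 lower in PT-ND (median −0.55, percentile 0.0200) and 4 higher and 3 lower in PT-D (median 0.06). Heat shock genes had 5 of 11 higher and 0 lower in PT-ND (median 0.58) and 0 either way in PT-D (median 0.04), with Hsp90aa1 at 413, 574, 1113 and 612 CPM. Endoplasmic reticulum stress genes had medians of 0.43 and −0.12, cholesterol synthesis of −0.50 and 0.02, and tubular injury of −0.67 and 0.09.

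The remaining lists had these preterm medians, non-diabetic first and diabetic second: female-biased genes −0.91 and −0.39 (3 genes), vitamin D and phosphate handling −0.36 and −0.26 (8 genes, percentiles 5.38 and 0.74), lipogenesis 0.05 and −0.26 (percentiles 66.6 and 2.03), matrix genes 0.02 and −0.25 (percentiles 58.8 and 1.34), nephron development 0.12 and −0.30, senescence −0.15 and 0.14, glucose and polyol handling −0.22 and 0.12, ketone body metabolism 0.12 and −0.14, hypoxia targets −0.04 and −0.05, cell cycle 0.02 and 0.03, and mitochondrially encoded transcripts 0.10 and 0.11. Within S1 and S2 clusters the first vitamin D value was 0.22, and under 25% mitochondrial counts the last mitochondrial one was −0.055. The others were p53 targets 0.11 and 0.11, gluconeogenesis 0.07 and 0.19, glycolysis 0.27 and 0.11, respiratory chain 0.07 and 0.18, oxidative stress 0.08 and 0.21, endocytosis −0.25 and −0.06, and solute transporters 0.07 and −0.11. Means without diabetes were opposite in sign to the medians for p53 targets (−0.27), oxidative stress (−0.20), solute transporters (−0.06), lipogenesis (−0.05), matrix (−0.15) and nephron development (−0.51). Across 3452 genes the preterm effects with and without diabetes had a Pearson r of −0.0587 and a Spearman rho of −0.0522, with the same sign in 50.6%.

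The final comparison asks whether the diabetic response differed with birth, as the log2 ratio of PT-D to PT-ND minus that of T-D to T-ND. Interferon-inducible genes were first among the positive differences: Gbp5, a guanylate-binding protein, at 544, 3.49, 1.69 and 6.74 CPM (8.44, counting interval 7.72 to 9.21), Iigp1, an immunity-related GTPase, at 1276, 19.3, 7.63 and 43.7 CPM (8.35, 7.96 to 8.77), then the fibrinogen gene Fgg (7.69) and Gbp2 (7.56). Pik3c2g, a lipid kinase, was at 440, 1.26, 303 and 259 CPM (7.39, 6.89 to 7.99), low in T-D alone. Among the negative differences were Hsd11b1, which regenerates active glucocorticoid, at 4.93, 77.2, 154 and 28.8 CPM (−6.09, −6.61 to −5.66), then Ttr (−5.50), Glt1d1 (−5.07) and Ctnna2 (−3.91). Hsd11b1 is among the 10 genes that lead cluster 19, which held 7, 258, 448 and 192 cells. Glt1d1 and Ctnna2 are among those of cluster 16, which held 3, 54, 254 and 62. For these genes a difference in response was not separated from the mix of clusters. By list, the median difference was 5.33 for interferon response, 4.13 for class I presentation, 3.68 for inflammatory genes, 2.45 for immediate early genes, −1.72 for male-biased genes and 0.15 for p53 targets. Of the positive differences named here, T-ND set those of Gbp5, Iigp1, Gbp2 and Fgg, being at least 10 times the level of each other library.

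In other cell classes the interferon response followed the same order of directions. Its median log2 ratio for the diabetic comparison, term then preterm, was −0.82 and 0.68 in the thick ascending limb (24 genes), −2.58 and 0.90 in the distal convoluted and connecting tubule (24 genes), −1.02 and 0.74 in macrophages, monocytes and dendritic cells (27 genes), −1.24 and 1.79 in neutrophils (27 genes) and −0.81 and 1.66 in endothelium (27 genes). In neutrophils Ifit1 was at 710, 252, 75.6 and 1094 CPM and Isg15 at 3127, 1025, 557 and 2717. Endothelial cells, of which PT-D held 37, had Isg15 at 2244, 1349, 803 and 4493 CPM. PT-ND against T-ND gave medians of −2.49, −3.18, −1.34, −2.12 and −1.26 in the same order of classes, and PT-D against T-D gave −0.92, 1.25, 0.50, 1.03 and 1.20. With cells under 25% mitochondrial counts alone, the thick ascending limb value for PT-D against T-D was 0.16.

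In the thick ascending limb, Ranbp3l was higher in both diabetic libraries (31.5, 162, 116 and 1438 CPM), as were Sycn (0.731, 25.9, 13.1 and 212) and Ltc4s (1.46, 33.4, 3.57 and 42.4), each with 1 or 2 UMIs in T-ND. Pappa2, a protease that frees insulin-like growth factors, was lower, at 58.5, 6.82, 35.1 and 0 CPM, at least 2.76-fold lower in PT-D than in PT-ND against a floor of 3 UMIs. Tagln2 and Samd4 were the other lower genes. Colec12, Sycn and Atp4a were higher and H2-T22, Rsad2 and Clu lower in both preterm libraries, with Clu, a chaperone linked to injury, at 328, 132, 57.7 and 21.2 CPM. For the difference in response, the chemokine gene Ccl20 was at 224 CPM in T-ND and 0 elsewhere, at least 109-fold lower in T-D and at least 125-fold lower in PT-ND; Olfm4, Ipcef1 and Nccrp1 also led. Inflammatory genes had medians of −2.00 and 1.62 for the diabetic comparisons (11 genes; the second 0.49 over members with 1 UMI or more) and −3.92 and −0.35 for the preterm ones. Sodium, chloride and potassium transport had medians of 0.34 and −0.07, then 0.57 and −0.02 (18 genes), with the sodium cotransporter gene Slc12a1 at 6298, 9349, 10686 and 10710 CPM. T-ND cells lay in clusters 6 and 9 and the others in 6 and 18, PT-D held 114 cells, and Sycn was not higher in PT-ND (log2 ratio −0.14) under 25% mitochondrial counts.

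Median log2 ratios of all genes were away from 0 by over 0.1 in these smaller classes, and the list medians given for them are not corrected for it; the endothelial matrix median at term and the neutrophil heat shock median in PT-ND against T-ND lie below the values that follow. They were 0.18 (diabetic, term) and 0.17 (preterm, non-diabetic) in the thick ascending limb, and −0.10 (diabetic, preterm) and −0.13 (preterm, diabetic) in the distal convoluted and connecting tubule. They were 0.22 (diabetic, term) and 0.25 (preterm, non-diabetic) in macrophages, monocytes and dendritic cells, and 0.12 and 0.22 for the same pair of comparisons in endothelium. In neutrophils they were −0.18 (diabetic, preterm), 0.45 (preterm, non-diabetic) and 0.18 (preterm, diabetic).

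In distal convoluted and connecting tubule cells, the genes named as lower in both diabetic libraries were Fxyd4, Kit and Kif26b. Fxyd4 and Kit are markers of collecting duct cells, which formed no cluster and were themselves fewer in the diabetic libraries (13, 2, 7 and 0 principal and 6, 1, 6 and 1 intercalated cells). Fxyd4, a regulator of the sodium pump, was at 311, 2.00, 49.3 and 0 CPM, Kit at 35.0, 0, 57.0 and 0 (at least 5.83-fold and 3.56-fold lower), and Kif26b at 54.4, 0, 53.1 and 0 (at least 9.06-fold and 3.32-fold lower). Of the 23 genes of sodium, chloride and potassium transport, 4 were higher and 5 lower at term (median 0.00, mean −0.54), and 2 higher and 12 lower in the preterm pair (median −0.62, percentile 0.110). Among them were the sodium channel subunit genes Scnn1b (192, 52.0, 83.0 and 37.4 CPM) and Scnn1g (187, 38.0, 108 and 32.1) and Hsd11b2 (408, 8.01, 99.8 and 26.7). Each of these is also a principal cell marker, so that a change in cell mix cannot be told apart from regulation. Slc12a3, the thiazide-sensitive cotransporter, was at 6035, 8085, 8960 and 5845. Fbxo32, Mtr and Lrrc52 were higher in both, Fbxo32 at 19.4, 90.1, 24.6 and 102 CPM. Colec12 was at 0, 0, 363 and 219 CPM, at least 62.2-fold and 36.5-fold higher in the preterm libraries, together with Slc26a4, an intercalated cell marker, and Iyd. Egfem1 (779, 160, 12.96 and 0 CPM), the calcium channel gene Trpv5 (311, 32.0, 28.5 and 0), a connecting tubule marker, and Cwc22 were lower in both. Iigp1, Apoa2, Prox1 and Gpcpd1 led the difference in response. PT-D held 96 of these cells, only 13 of them in the deeper cluster 3, its long genes were lower than its short ones against PT-ND by −0.76, and Fbxo32 was not higher there under 25% mitochondrial counts (log2 ratio −0.15).

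Macrophages, monocytes and dendritic cells of both diabetic libraries had more Mrc1, the mannose receptor of tissue macrophages (4.73, 50.8, 33.1 and 195 CPM), and less Ccl17 (194, 9.85, 66.1 and 1.34) and Il12b (69.4, 15.9, 33.9 and 0), products of activated dendritic cells. Cluster 14, led by C1qa, C1qb and C1qc, held 24, 71, 49 and 51 of the cells and cluster 5 the other 86, 93, 94 and 104. S100g (1.58, 73.5, 4.96 and 358 CPM) is a marker of the connecting tubule, and its ratio turned to −0.24 in the preterm pair without the 5% of cells of highest doublet score. Airn, which lies antisense to another gene, was higher and Ccl22 lower as well. In the preterm libraries Hal (7.89, 7.58, 86.0 and 45.6 CPM), Add3 and Mecom were higher and Ear2, Cwc22 and Ggct lower. The difference in response was led by Chil1 and AA467197 above and H2-M2 and Tpm3-rs7 below. Inflammatory genes had diabetic medians of −0.44 and 0.17 (20 genes), with Il1b at 1100, 421, 312 and 134 CPM, class II presentation −0.26 and −0.20 (8 genes), and heat shock genes −0.16 and 0.67 (12 genes). Over the alternatives the preterm inflammatory median ran from −0.19 to 0.21. The class II medians ran from −0.48 to 0.09 at term and from −0.28 to 0.62 in the preterm pair. Without the highest doublet scores Ccl22 was not lower at term (0.06) and Mecom not higher in PT-D (−1.001).

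Neutrophils of both diabetic libraries had higher levels of Gsr, glutathione reductase, at 33.5, 1131, 61.9 and 697 CPM, and of the phosphodiesterase gene Gdpd3 at 11.2, 342, 41.2 and 204 CPM. Apobec1, an RNA-editing enzyme, was also higher, and Tbxas1, Smg6 and Slc16a3, a lactate exporter, were lower. Both preterm libraries were lower in Def8 (561, 200, 3.44 and 7.15 CPM), Tnf (130, 92.3, 27.5 and 21.4) and Slc15a2, at 93.0, 112, 0 and 0 CPM (at least 18.0-fold and 10.4-fold lower), and higher in Trim30d, Rab28 and Mlxip. Fap, Bst2, Lypd6b and Camk2g led the difference in response, Bst2 at 149, 7.69, 12.03 and 122 CPM. Heat shock genes had diabetic medians of −1.14 and −0.35 and preterm medians of 0.41 and 1.17 (8 genes). Over the alternatives the value of 0.41 ran from −0.03 to 1.11, and the last was 0.47 under 25% mitochondrial counts. Each library held 91 to 176 neutrophils, so that genes at a few CPM rest on single UMIs.

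Endothelial cells were too few in PT-D, at 37, for genes to be named by the rule. The genes given here illustrate lists and were picked after values were seen, and 3 UMIs stand for 28.5 CPM in PT-D. Genes of endothelial activation and angiogenesis had 8 of 28 higher and 3 lower in T-D against T-ND (median 0.30) and 3 higher and 5 lower in PT-D against PT-ND (median −0.35). Edn1, the vasoconstrictor endothelin, was at 63.2, 229, 310 and 332 CPM, Nos3, endothelial nitric oxide synthase, at 263, 84.3, 60.6 and 190, and the leukocyte adhesion gene Sele at 1090, 1397, 1481 and 199. Preterm medians were 0.47 without and −0.27 (mean 0.05) with diabetes. Inflammatory genes had medians of 0.41 (mean −0.42) and −0.85 for the diabetic comparisons (14 genes), heat shock −0.41 and 0.76 (12 genes) and matrix 0.07 and −0.38 (20 genes).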

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

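Of the tests in this part, that for RNA of immune cells was set before its result was seen, and the other 6 were chosen only after the result was seen.

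Interferon response genes stood out because the diabetic comparison went down at term and up in the preterm pair in each of the 6 classes measured; with 1 animal per group the difference was not tested. The 6 classes come from the same 4 animals, so that they are not independent of each other. The median difference, preterm minus term, was 5.33 in the proximal tubule, 1.61 in the thick ascending limb, 4.64 in the distal convoluted and connecting tubule, 1.91 in macrophages, monocytes and dendritic cells, 3.09 in neutrophils and 2.498 in endothelium. The same opposition, also untested, was seen in the proximal tubule for class I presentation (4.13), inflammatory genes (3.68) and immediate early genes (2.45), and for inflammatory genes in the thick ascending limb (3.44). Immediate early genes in macrophages, monocytes and dendritic cells differed by 0.45 (−0.25 and 0.14, the latter −0.0061 with the mean over cells).

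For the immune genes of T-ND proximal tubule cells, RNA of immune cells, free or from doublets, was tested first. Cd74 at 1599 CPM would need 20.1% of the RNA to come from macrophages, yet the 17 abundant myeloid genes used lay at a median of 0.00599 of the level this share gives, with Lyz2 at 9.47 CPM against 2329 needed. Of 20 genes listed, S100a8, S100a9 and Retnlg were left out, with under 60 UMIs in T-ND macrophages (17, 5 and 1). They lay at 0.72, 2.86 and 0.84 of that level. The 17 genes used argue against immune cell RNA as the source. A state of the T-ND animal or library apart from its group stays open, since T-ND is 1 library: the preterm pair, which does not use it, had an interferon median of 1.98, and no value separates this animal from its group. Birth and diabetes, which the design names, also stay open as untested.

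Other lists went in opposite directions and the difference was not tested: male-biased genes in the proximal tubule by −1.72 (0.58 at term and −1.26 in the preterm pair, but −0.22 and −0.40, with no opposition, within S1 and S2 clusters) and heat shock genes in endothelium by 1.07 (−0.41 and 0.76). Shares also did so. The share of proximal tubule cells differed by 20.04 percentage points (−7.06 and 12.98), that of T and NK cells by −2.89 (2.03 and −0.859) and that of plasma cells by −1.78 (0.427 and −1.36). With each library clustered by itself, the plasma cell name was given in T-D alone, while 2.58% of PT-ND took the B cell name. Whether those are the same PT-ND cells under another name was not checked. Barcodes with 50% or more mitochondrial counts, which the comparisons do not use, made up 62.9% of T-D and 53.5% of PT-D, above the 29.5% and 16.5% of the non-diabetic libraries. In both diabetic libraries most of these barcodes also had under 200 genes.

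The p53 targets higher in proximal tubule cells of both diabetic libraries were weighed against cell quality, segment mix and gene span, over the same 12 members. Intervals of the drops are paired bootstraps over members. With cells matched on mitochondrial share the smaller of the 2 medians was 0.81, with drops of −0.10 (−0.38 to 0.04) and 0.01 (−0.15 to 0.17). Before matching, these cells already had median shares of 25.8, 27.1, 26.2 and 29.2%, and the removed barcodes are not reached by it. The matching therefore cannot decide on cell quality, which stays open. With the median of each span quartile taken off, the smaller median was 0.68, with drops of 0.15 (−0.06 to 0.21) and 0.13 (−0.02 to 0.17). No drop could exceed the highest quartile medians, 0.21 at term and 0.17 in the preterm pair, so the outcome of this test was set before it ran. The values show only that the span trend was smaller than the p53 medians of 0.84 and 0.81. A different mix of segments also stays open. The smallest of the 4 medians within segments was 0.36, in S3 clusters at term, where the drop of 0.47 ran from −0.53 to 0.56; with members measured in those clusters it was 0.45, and the fixed members and the interval of the drop were adopted after both were seen. Diabetes, streptozotocin itself and differences between single animals also stay open.

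Genes at least 3-fold apart between pairs of libraries in 3 or more classes numbered 4: Colec12, Cwc22 and Slc15a2 by birth and Gdpd3 by diabetes. An earlier limit of 8-fold in each class gave 0 genes and was relaxed, and a minimum of 10 genes for a verdict was set after the count was seen. The split that crosses birth and diabetes held 0 genes, and 0% of the 4 had another gene of the same split within 2 Mb. With 4 genes, inherited variants that differ between the animals and an effect of birth or diabetes cannot be told apart.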

How the results depend on the processing

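The removal of the 5% of cells with the highest doublet scores and the matching of cells on mitochondrial share were chosen after seeing the data; the other 12 alternatives were set before the data were examined. No paired analysis was possible because groups share fewer than 2 replicate numbers; a fit blocked by birth group, with 1 residual degree of freedom, was left out. Every alternative gave values. Of 240 values for cell shares, 185 stayed inside the counting interval and 55 moved beyond it; a reversal was not defined for shares. Of 3555 values for list medians, 3408 stayed inside the bootstrap interval over members, 137 moved beyond it without counting as reversed, and 10 reversed, which counts only lists whose interval excludes 0. Lists whose interval holds 0 changed sign in 181 further values, so that 96 of 285 list medians changed sign at least once. Of 2290 values for named genes, 1904 stayed inside the counting interval, 367 moved and 19 reversed. For the values below, the cause was not tested.

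With cells under 25% mitochondrial counts, the proximal tubule share was 55.2% in T-ND, 44.8% in T-D, 54.8% in PT-ND and 63.8% in PT-D. PT-D against T-D then gave −0.055 for mitochondrially encoded transcripts in the proximal tubule, 0.16 for interferon response in the thick ascending limb and −1.38 for Mecom in macrophages, monocytes and dendritic cells. PT-D against PT-ND gave −0.15 for Fbxo32 in the distal tubule and −0.16 for S100g in macrophages, and PT-ND against T-ND gave −0.14 for Sycn in the thick ascending limb.

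The interferon response in the proximal tubule kept its direction in the settings that follow. Its median for PT-D against T-D was 1.13 at Leiden resolution 2, 1.15 without the highest doublet scores and 0.52 with a pseudocount of 10 CPM. That pseudocount gave 1.19 for PT-D against PT-ND, −3.16 for PT-ND against T-ND and 3.86 for the difference. S1 and S2 clusters alone gave 1.62, −3.60 and 4.32 in that order. S3 clusters alone gave −4.85 for T-D against T-ND, 1.46 for PT-D against PT-ND and −5.41 for PT-ND against T-ND.

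In macrophages, monocytes and dendritic cells, S100g was at −1.32 for T-D against T-ND with each library clustered by itself and −0.24 for PT-D against PT-ND without the highest doublet scores. The latter setting gave 0.057 for Ccl22 at term and −1.001 for Mecom in PT-D against T-D. Immediate early genes were at −0.0061 for PT-D against PT-ND with the mean over cells. In the proximal tubule, the cell cycle list was at −0.34 at term when members with 1 UMI or more were used.

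Male-biased genes in S1 and S2 clusters were at −0.22 for T-D against T-ND, −0.40 for PT-D against PT-ND and −0.26 for PT-ND against T-ND, and in S3 clusters at −0.75 for PT-D against PT-ND. Vitamin D and phosphate handling was at 0.22 for PT-ND against T-ND in S1 and S2 clusters. In S3 clusters, T-D against T-ND gave −0.025 for glycolysis, −0.077 for the respiratory chain, 0.13 for Gsap, 0.34 for Ubash3b, 1.42 for Ccser1, 3.18 for Hnf4g and 0.62 for Aoah. There, PT-D against T-D gave −0.11 for class I presentation, −0.26 for Apob and 1.30 for Snhg11, and PT-ND against T-ND gave 1.40 for Dock10, 3.22 for Zfp951, 3.06 for Snhg11 and 0.22 for Col6a6. Depth limits the small classes most: PT-D held 37 endothelial cells, 96 of the distal tubule and 114 of the thick ascending limb.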

Other observations

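No test in this part was planned, and the genes were picked after their values were seen. Class II antigen presentation genes, whose usual site is immune cells, were read in classes for which the list was not planned. In the proximal tubule 7 of 7 measured members were lower in T-D than in T-ND (median −4.87) and 7 of 7 lower in PT-ND than in T-ND (median −5.82), and in endothelium the same counts had medians of −6.70 and −5.94. In the proximal tubule Ciita, the master regulator of class II genes, was at 187, 1.40, 1.86 and 2.45 CPM, Cd74, the invariant chain, at 1599, 44.7, 16.7 and 32.3, and H2-Ab1 at 410, 15.1, 3.98 and 16.9. In endothelium H2-Ab1 was at 1269.96, 11.2, 40.4 and 19 CPM (2 UMIs in PT-D). The stress-inducible chaperone gene Hspa1b was at 2.00, 1.54, 46.5 and 1.43 CPM in the proximal tubule, high in PT-ND alone.

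Sycn (chromosome 7, 28540885 to 28542209) and Nccrp1 (chromosome 7, 28543596 to 28547254) are neighbours, and both were near 0 in the thick ascending limb of T-ND: Sycn at 0.731, 25.9, 13.1 and 212 CPM and Nccrp1 at 0, 330, 70.2 and 301. Gdpd3 was higher in both diabetic libraries in proximal tubule cells (1.07, 30.9, 1.44 and 18.8 CPM) as in neutrophils, and at 1.46, 66.2, 20.2 and 21.2 CPM in the thick ascending limb. In the distal convoluted and connecting tubule it was at 1.94, 36.0, 25.9 and 10.7 CPM, lower in PT-D than in PT-ND. Its cause was not tested.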
